A study of Mus musculus with 11 samples.

How the data were processed

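The data are 11 polyadenylated RNA libraries of the mouse liver cancer line EC4, from cells labelled MYC high or MYC low that were kept for 24 h in DMEM with 10 or 200 µM methionine. Per the labels' protocols, RNA was taken with a Qiagen kit and libraries were made with NEBNext Ultra II reagents. The files hold 1 signal value per gene and library, which the submitters deposited as normalized counts. The submitters' processing notes name FastQC, fastp, STAR, SAMtools, HTSeq and DESeq2 and the mouse build GRCm39, without versions or order. The annotation release, the strand setting and the parameters are not given in the sources used here, so overlapping genes on opposite strands may share reads. The values of each library were whole multiples of 1 step, and 100% of values came out as whole reads within 0.001. The step equalled the inverse of a size factor of 0.875 to 1.13 that median-of-ratios scaling over these 11 libraries gives from the 13969 genes above 0 in all of them. Columns of other samples numbered 0.

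Gene identifiers were matched to symbols with GENCODE M21, which belongs to the earlier build GRCm38. It served for symbols, transcript length and GC content, and no coordinates are printed because the builds differ. Of 55416 identifiers 52083 had a symbol. Genes with a mean normalized count of at least 10 were tested, 12909 in all, of which 12857 had a symbol. Recovered reads per library were 10858936 to 11747837 in MYC high cells at 200 µM, 11446651 to 12066545 in MYC low cells at 200 µM, 11788415 to 11965202 in MYC high cells at 10 µM and 12194511 to 13085689 in MYC low cells at 10 µM. A gene with 0 reads in a library has an upper 95% limit of 3 reads, or 2.65 to 3.43 normalized counts. For genes with 1 to 3 reads in a group, a ratio of pooled reads is given with an exact 95% counting interval. Eef1a1, the most abundant transcript, took 0.874% to 1.25% of the reads of a library.

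The deposited signal values were analysed as log2 of the value plus 1, a scale that understates fold changes of genes with low values. Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group, empirical Bayes moderation with a trend on mean expression (7 residual and 29.0 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes within each comparison, at 0.05. The comparisons were MYC high minus MYC low at 200 µM and at 10 µM, 10 minus 200 µM methionine in MYC high and in MYC low cells, and the interaction, which is the methionine response of MYC high minus that of MYC low cells. SE is limma's moderated standard error of a log2 difference, SD is that between libraries of a group, and adjusted p of single genes are limma's. The spread was pooled over groups, which assumes that the 2 libraries of MYC high cells at 200 µM vary like the others. Agreement between comparisons was set against independent lists and, where libraries were shared, against 100 simulated data sets without group differences.

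Gene lists were tested with camera at the preset correlation of 0.01, adjusted over the 30 lists with at least 5 tested members. These were the methionine cycle, methionine salvage and polyamines, amino acid transporters, RNA m5C methyltransferases, RNA m6A and cap methylation, DNA and protein methyltransferases, ribosome biogenesis, canonical MYC targets, cytosolic ribosomal proteins, the ATF4 response, aminoacyl-tRNA synthetases, serine and folate metabolism, nucleotide synthesis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes. Lists of the cell cycle, p53 targets, the unfolded protein response, glutathione and NRF2 targets, lysosome and autophagy, the type I interferon response, MHC class I presentation, immediate early and heat shock genes, and markers of hepatocytes, fetal liver and fibroblasts were tested in the same way. Lists of macrophage and endothelial markers had 3 and 4 tested members and were too small. Members were written from general knowledge, and some lists share members. The ATF4 list holds genes that are also in the transporter, synthetase or serine and folate lists, such as Slc6a9, Wars and Mthfd2. The MYC targets share Ncl, Npm1, Nop56 and others with the ribosome biogenesis list. Calls of lists that share members are not independent results. A list is called where its camera adjusted p is under 0.05, and single members are counted by limma.

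Genes are named by a rule. It covers 14 genes fixed by name (Myc, Nop2, Mat2a, Ahcy, Mtap, Slc7a5, Slc43a2, Atf4, Asns, Trib3, Odc1, Ncl, Afp and Alb), the 5 genes with the largest positive and negative differences in each comparison, up to 4 members of each list with the smallest adjusted p, and members against the direction of their list or not passed where they are named as such. The genes with the largest differences had a mean normalized count of at least 100 over all libraries, an adjusted p under 0.05 and, outside the interaction, no overlap between the libraries of both groups, and predicted genes were left out. Some genes that the rule covers are not reported here. Genes outside the rule are said to be chosen after their values were seen. Groups, comparisons, lists, the naming rule and the alternatives were written before the data were examined, apart from the tests and counts said to be later. The counts of at least 2-fold changes were added later.

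The alternatives were other normalizations (TMM, total-sum), edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other pseudocounts (0.5 and 5), no filter or a mean of at least 50, limma with robust moderation, without a trend or with a replicate block, fits with 2 groups alone and fits without each library in turn. List tests were repeated with the correlation estimated from the data and with fry. A smooth trend on transcript length and GC content (splines with 5 degrees of freedom) was removed as an alternative written later. Both were those of the longest annotated transcript of a gene, which need not be the one expressed. Medians of lists were given bootstrap standard errors over genes (2000 draws). The code was tested on simulated data with genes changed by known folds and a list shifted by 0.3 on the log2 scale. In each comparison of 2 groups, 12909 genes were simulated. Limma recovered 54% of 50 genes seeded with the smallest fold (1.25) and 96% of 50 seeded 2-fold for the MYC labels at 200 µM. The shares were 64% and 96% for the labels at 10 µM. They were 58% and 92% for the media in MYC high cells and 60% and 90% in MYC low cells. False calls made up 9.24%, 3.43%, 6.25% and 4.55% of calls in the same order. The 5% aimed at was exceeded in both of these comparisons that use the group of 2 libraries. The interaction, which also uses that group, was not simulated. Far fewer genes were changed in the simulation than passed in the data, so these shares of false calls do not carry over. With no list seeded 0 of 30 were called, and with 1 seeded that list was called each time among 3, 1, 2 and 3 called. The simulated genes were drawn independently of each other. The list result therefore does not show how often lists whose members vary together are called falsely. Replicate 1 of MYC high cells at 200 µM was not analysed here. Transcripts, splicing and a human MYC transgene were not measured, since the values are per mouse gene.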

Results

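Polyadenylated RNA was sequenced from EC4 cells, a mouse liver cancer line in which MYC can be switched on or off, after 24 h in DMEM holding 10 or 200 µM methionine. The labels give 200 µM as the methionine of the growth medium. MYC high and MYC low are used here as the names that the labels give the libraries. The series title concerns methionine use and the methyltransferase NOP2 in liver tumours driven by MYC, and the 4 groups allow the MYC state to be compared in each medium and the media to be compared in each MYC state. There were 2 libraries of MYC high cells at 200 µM, numbered 2 and 3, and 3 libraries in each of the other groups. Replicate 1 of MYC high cells at 200 µM was not analysed here. Each library held 10858936 to 13085689 reads on genes, and 17395 to 18462 genes had a read. Of 55416 gene identifiers, 12909 had a mean normalized count of at least 10 and were tested.

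Libraries of 1 group lay close together. The principal component with the largest share carried 50.7% of the variance between libraries and the next carried 35.9%. Replicate pairs had Pearson correlations of at least 0.993 across genes, and the biological coefficient of variation estimated from the recovered reads was 2.78%. Replicates still differed by more than sampling noise, with a chi-square per gene of 1.40 to 2.74. Each was counted as its own sample, though this excess does not show that they came from separate cultures. The labels do not say that replicates came from separate cultures, and p-values therefore measure the spread between these libraries, which may be technical. Mitochondrially encoded transcripts took 0.845% ± 0.0624 of reads in MYC high cells at 10 µM (SD, n = 3) and 0.854% ± 0.0216 in MYC high cells at 200 µM (SD, n = 2). The share was 1.54% ± 0.0319 in MYC low cells at 10 µM and 1.71% ± 0.0363 in MYC low cells at 200 µM (SD, n = 3 each).

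**Figure D1:**
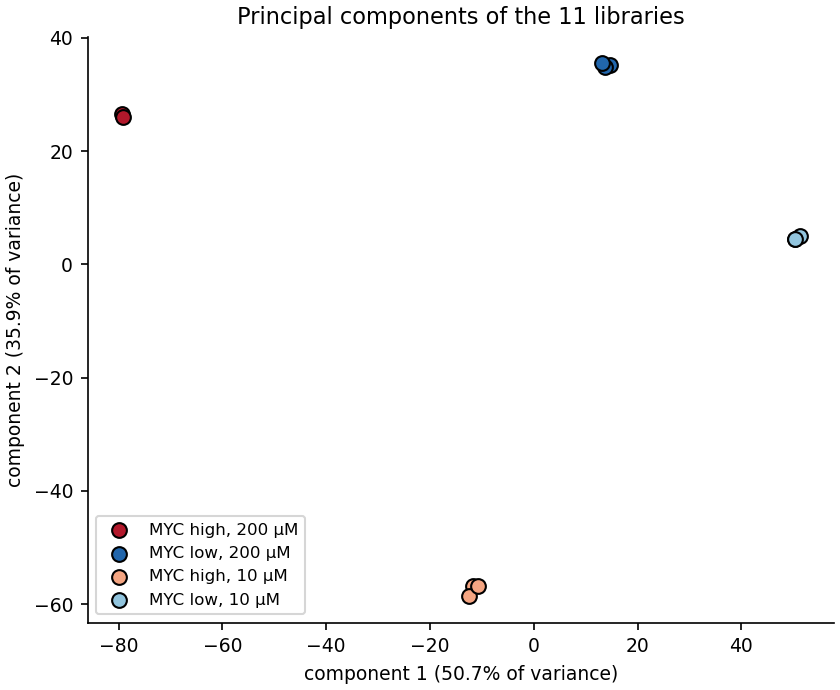
Each point is 1 of the 11 libraries, placed by its scores on the leading principal components of the log2 normalized counts, which carry 50.7% (horizontal axis) and 35.9% (vertical axis) of the variance. Colours mark the 4 groups, and the libraries of a group overlap or nearly overlap.

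The mouse Myc transcript (ENSMUSG00000022346) separated the MYC labels at 200 µM but not at 10 µM. Myc stood at 2089 ± 106 normalized counts in MYC high (SD, n = 2) and 1136 ± 31.3 in MYC low libraries (SD, n = 3) at 200 µM, a difference of 1.84-fold (log2 0.88, SE 0.070, adjusted p = 5.99e-14). At 10 µM it stood at 336 ± 39.2 and 336 ± 13.5 (SD, n = 3 each), with an adjusted p of 0.949 and a 95% interval of the log2 difference from −0.13 to 0.12. The lower methionine went with less Myc in both states, by −2.64 (SE 0.070) on the log2 scale in MYC high and −1.76 (SE 0.063) in MYC low cells, and the drop was larger in MYC high cells (interaction −0.88, adjusted p = 2.80e-10). Reads of a human MYC transgene, if the line carries one, would be counted only in part against mouse genes, so this transcript checks the labels only in part. Every direction given at 10 µM rests on the labels.

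**Figure D2:**
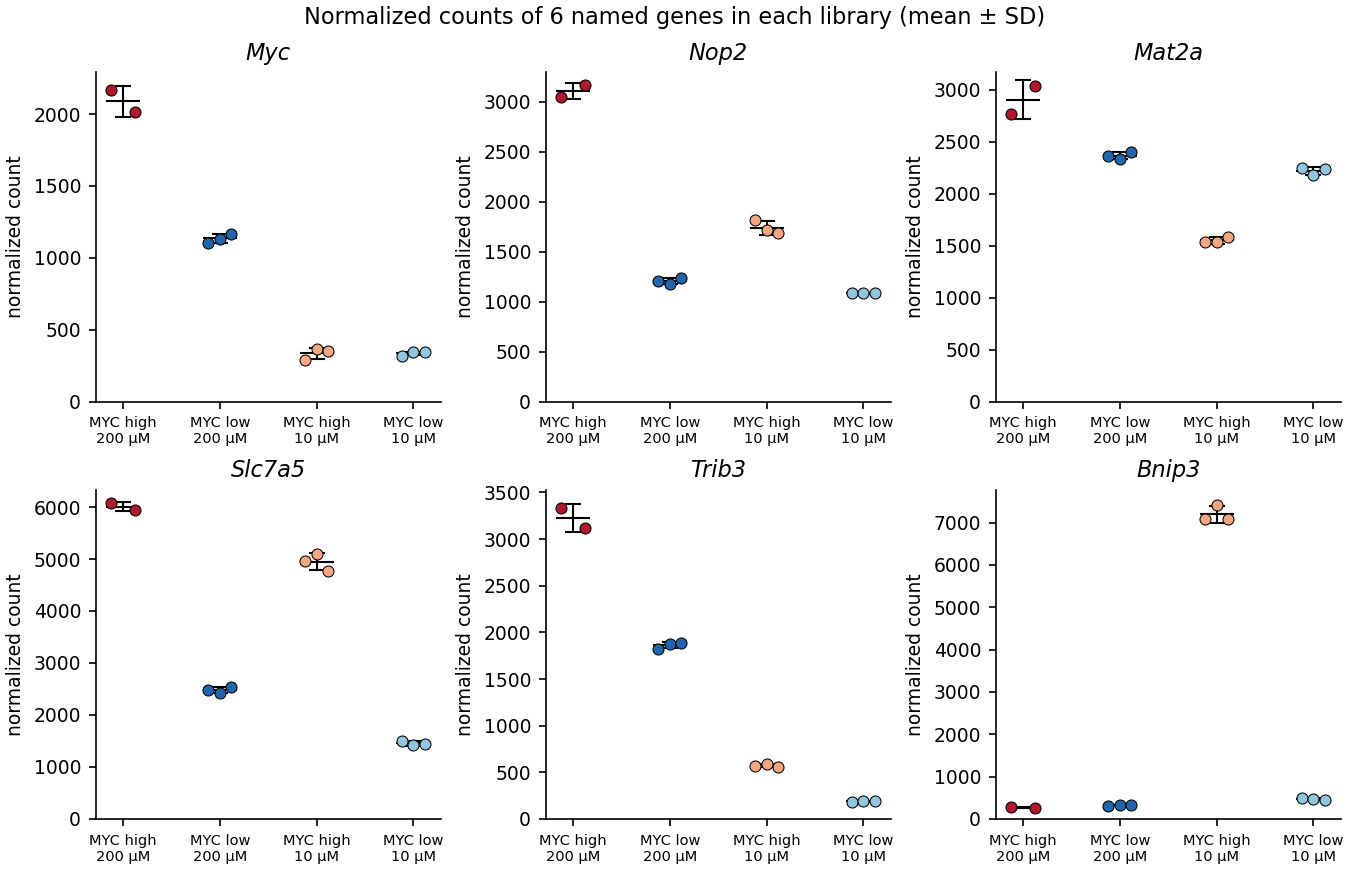
Normalized counts (vertical axes, from 0) of Myc, Nop2, Mat2a, Slc7a5, Trib3 and Bnip3 in the libraries of the 4 groups (horizontal axes). Points are libraries, the long bar is the mean and the whiskers are the SD (n = 2 in MYC high at 200 µM, n = 3 elsewhere), and Bnip3 stood at 7197 ± 196 in MYC high cells at 10 µM against 267 to 471 in the other groups.

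At 200 µM methionine, ribosome biogenesis, aminoacyl-tRNA synthetase and nucleotide synthesis genes were higher in MYC high than in MYC low libraries, while interferon and glutathione genes were lower. All 60 ribosome biogenesis genes measured were higher, with a median log2 difference of 1.06 (camera adjusted p = 2.40e-24). Nop2 (ENSMUSG00000038279), which methylates ribosomal RNA in the nucleolus, stood at 3108 ± 81.4 normalized counts (SD, n = 2) against 1209 ± 28.5 (SD, n = 3), 2.57-fold higher (log2 1.36, SE 0.044, adjusted p = 1.23e-25). Synpo, which encodes the actin-associated protein synaptopodin, stood at 3.79 ± 2.13 against 390 ± 23.3 (log2 −6.42, SE 0.24). Of 12909 genes tested with limma, 9600 passed the threshold of 0.05 on the adjusted p, 4746 of them higher and 4854 lower. At least 2-fold differences made up 2442 of these, 877 higher and 1565 lower.

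Among the enzymes and carriers fixed by name, Ahcy, which clears S-adenosylhomocysteine, was higher by 1.09 on the log2 scale (SE 0.044) and Mtap of methionine salvage by 0.57 (SE 0.044). Mat2a (ENSMUSG00000053907), which makes S-adenosylmethionine, was higher by 0.29 (SE 0.041). Slc7a5, a carrier of large neutral amino acids, was 2.42-fold higher at 6008 ± 93.9 against 2485 ± 60.1, whereas Slc43a2, another carrier of this kind, was lower at 80.8 ± 2.77 against 459 ± 36.5 (log2 −2.49, SE 0.101). Atf4 (0.69), Asns (0.67) and Trib3 (0.79) of the amino acid response, Odc1 of polyamine synthesis (0.83), Ncl (1.06) and the fetal liver gene Afp (0.79, SE 0.127) were also higher on the log2 scale. Alb, the albumin gene, had 0 reads in all 11 libraries, which allows up to 2.65 to 3.43 normalized counts in a library, so it was not detectable at this depth. The largest positive log2 differences among well expressed genes belonged to Sprr1b (4.14, SE 0.102), Slc35f2 (3.33), Angptl8 (3.02), Hspa1b (2.93) and Abcb1b (2.86). The largest negative ones, besides Synpo, belonged to Tns1 (−6.39, SE 0.121), Ly6a (−5.22), Lgals3bp (−4.92) and Cldn2. Cldn2 had 2 reads in the MYC high libraries, and its ratio of MYC low to MYC high was 68.6 with a counting interval of 18.8 to 569. Sprr1b, Hspa1b and Ly6a have near-identical relatives with which reads can be shared, so their values are uncertain.

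Of the canonical MYC targets, 41 of 43 were higher and 2 lower (median log2 0.96, camera adjusted p = 2.13e-17), among them Tfrc (1.99), Nop56 (1.83) and Pa2g4 (1.77), while Hk2 (−0.42) and Ccnd2 (−0.17) went against the list. Of 76 cytosolic ribosomal protein genes, 75 were higher and 1, Rpl37a (0.09, adjusted p = 0.0541), did not pass (median 0.59), led by Rps27a and Rpl12 (1.03 each, SE 0.033 and 0.035). The ribosomal protein call, at a camera adjusted p of 6.67e-23, was lost at an adjusted p = 0.138 with an estimated correlation, and pseudogene copies make single members uncertain. Cytosolic aminoacyl-tRNA synthetases were higher in 18 of 20 (median 0.64, adjusted p = 8.49e-08) with Yars at 1.10 and Farsa at 1.19, and serine and folate one-carbon genes in 19 of 23 (0.65, adjusted p = 2.17e-06) with Psat1 at 1.47 and Shmt1 at 1.58. Nucleotide synthesis genes were higher in 27 and lower in 4 of 35 (0.68, adjusted p = 8.49e-08), with Umps at 2.02 and Uck2 at 1.83. The ATF4 amino acid response list had 30 members higher and 3 lower of 36 (0.74, camera adjusted p = 2.74e-08, adjusted p = 0.0530 with an estimated correlation), with Psat1 and Ddit4 (1.48) higher and Cdsn (−2.71), Gdf15 (−0.43) and Jdp2 (−0.54) against the list.

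Methionine salvage and polyamine genes were higher in 11 and lower in 6 of 18 (median 0.64, camera adjusted p = 0.0117, adjusted p = 0.279 with an estimated correlation), led by spermidine synthase, Srm (1.89). RNA m6A and cap methylation genes were higher in 21 of 27 (0.37, adjusted p = 2.79e-04) with Ythdc1 at 1.47, and DNA and protein methyltransferases in 27 of 37 (0.45, adjusted p = 1.69e-04) with Prmt1 at 1.18. The adjusted p of these lists was 0.0716 and 0.115 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes were higher in 35 of 43 (0.36, adjusted p = 1.86e-06) with Cycs at 1.12, while all 10 mitochondrially encoded genes were lower (−1.03, adjusted p = 4.52e-06) with mt-Nd2 at −1.32. These calls were lost at an adjusted p = 0.199 and an adjusted p = 0.152 with an estimated correlation. Cell cycle genes (29 of 46 higher, 0.43, Mcm5 1.44), p53 targets (15 of 23, 0.56, Mdm2 1.26), unfolded protein response genes (14 of 23, 0.36, Hspa5 1.53) and glycolysis genes (12 of 21, 0.26, Pkm 1.10) had camera adjusted p of 1.47e-05, 4.05e-04, 5.56e-03 and 0.0363. With an estimated correlation their adjusted p was 0.115, 0.0712, 0.0716 and 0.387.

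The lists lower in MYC high libraries were those of glutathione and NRF2 targets (20 of 28 lower, median −0.64, camera adjusted p = 4.52e-06), with Ephx1 at −2.91 and Abcc3 at −2.80, and the type I interferon response (17 of 19 lower, adjusted p = 9.63e-04), with Samd9l at −3.31. The interferon median was −1.75, and −1.40 with the 2 members that had 1 read in MYC high libraries placed at the limit of their counting interval nearest to no change. These members were Xaf1 and Oas3, chosen after their values were seen, with ratios of MYC low to MYC high of 57.5 (counting interval 10.1 to 2294) and 10.8 (1.70 to 449). Lysosome and autophagy genes were lower in 26 of 37 (−0.63, adjusted p = 1.96e-06) with Ctsl at −1.64, fatty acid synthesis genes in 14 of 22 (−0.32, adjusted p = 0.0350) with Scd1 at −2.10, and fibroblast and stellate cell markers in 3 of 7 (−0.55, adjusted p = 0.0291) with Fn1 at −3.15. The adjusted p of these lists was 0.0953, 0.0953 and 0.103 with an estimated correlation. Few cell markers passed the filter, 7 of 20 listed fibroblast genes and 8 of 48 hepatocyte genes. The median marker of the whole lists stood at 1.43 and 0 normalized counts, so most were near 0. Of 38 listed interferon genes 19 were tested, and the median of the whole list was 10.5 normalized counts, close to the filter of 10. The remaining 9 lists were not called, among them the methionine cycle (6 higher, 4 lower of 11, adjusted p = 0.461), amino acid transporters (9 higher, 6 lower of 17, adjusted p = 0.180), cholesterol synthesis (7 higher, 11 lower of 24, adjusted p = 0.190), immediate early and heat shock genes (13 higher, 8 lower of 23, adjusted p = 0.117) and hepatocyte genes (1 higher, 4 lower of 8, adjusted p = 0.628). RNA m5C methyltransferases had Nsun2 (1.28) and Nop2 higher and Nsun4 (−0.64) lower at a camera adjusted p of 0.180. In that list the sign of the median differed from that of the mean (0.28). In every comparison but that of media in MYC low cells, counts adjusted over the list alone differed from those over all genes by at most 1 member per direction.

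At 10 µM methionine the comparison of the MYC labels showed glycolysis genes far above MYC low levels, beside higher ribosome biogenesis genes and MYC targets. Of 21 glycolysis genes, 19 were higher in MYC high libraries and 2 did not pass (median 2.83-fold, camera adjusted p = 7.41e-15). Pgk1, Ldha, Aldoa and Pdk1 were higher by 2.66 (SE 0.028), 2.06 (SE 0.027), 1.81 (SE 0.027) and 2.97 (SE 0.047). Bnip3 (ENSMUSG00000078566), a mitophagy receptor, stood at 7197 ± 196 against 471 ± 29.2 normalized counts (SD, n = 3 each), a 15.3-fold difference (adjusted p = 2.35e-38). Of the 12909 genes, 9232 passed with limma, 4612 higher and 4620 lower, and 1851 differed by at least 2-fold, 828 higher and 1023 lower.

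Nop2 was 1.60-fold higher in MYC high libraries at 10 µM (1740 ± 68.9 against 1086 ± 5.03, log2 0.68, adjusted p = 7.12e-18). Ahcy (1.13), Mtap (0.40), Slc7a5 (1.76, SE 0.034), Atf4 (0.52), Asns (1.26), Trib3 (1.57), Odc1 (1.05), Ncl (1.24) and Afp (1.43, SE 0.113) were higher on the log2 scale, and Mat2a (−0.52, SE 0.037) and Slc43a2 (−2.89, SE 0.090) were lower. Selenbp1, which encodes a selenium-binding protein and has a close paralog, stood at 1321 ± 69.0 against 10.3 ± 0.911 (log2 6.87, SE 0.28). Stbd1 (4.51), Ankrd37 (4.15) and Reep6 (3.74) followed Selenbp1 among the largest positive log2 differences, with Bnip3 between them (3.93). The largest negative ones were those of Synpo (−7.37, SE 0.22), Pmepa1 (−5.55), Sned1 (−4.79), Thbs1 (−4.76) and Ly6a (−4.64), of which Thbs1, the thrombospondin 1 gene, stood at 273 ± 36.9 against 7407 ± 237.

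Of 76 ribosomal protein genes, 75 were higher and 1 did not pass (median 0.99, camera adjusted p = 2.17e-39, adjusted p = 0.0797 with an estimated correlation), with Rpl3 at 1.23 and Rps26 at 1.26. Ribosome biogenesis genes were higher in 53 and lower in 1 of 60 (0.72, adjusted p = 1.77e-17) with Npm1 at 1.66 and Pno1 (−0.22) against the list. MYC targets were higher in 42 of 43 (0.86, adjusted p = 1.39e-19), and Mcm4 did not pass (0.02, adjusted p = 0.717). The synthetases (18 of 20 higher, 0.70, Kars 1.01), serine and folate genes (17 of 23, 0.52, Mthfd1l 2.04), nucleotide synthesis genes (25 of 35, 0.47, Uck2 2.63) and cholesterol synthesis genes (18 of 24, 0.62, Stard4 2.37) had camera adjusted p of 6.79e-08, 1.96e-06, 5.17e-07 and 2.15e-04. Oxidative phosphorylation genes were higher in 40 of 43 (0.54, adjusted p = 7.57e-13, Cyc1 1.01), ATF4 genes in 26 of 36 with 7 lower (0.50, adjusted p = 7.84e-07, Aldh18a1 2.18) and cell cycle genes in 36 of 46 (0.45, adjusted p = 1.47e-07, Mybl2 1.66). With an estimated correlation these adjusted p were 0.104, 0.0797 and 0.0797. Salvage and polyamine genes (12 of 18 higher, 0.47), m6A and cap methylation genes (13 of 27, 0.15) and DNA and protein methyltransferases (21 of 37, 0.17) were called at 3.64e-03, 0.0274 and 0.0278. Each was lost at an adjusted p = 0.253, 0.219 and 0.320 with an estimated correlation.

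Lysosome and autophagy genes were lower in 31 of 37 at 10 µM (median −0.78, camera adjusted p = 1.38e-13), with Ctsl at −2.09 and Ctsd at −1.29, 2 lysosomal proteases. The mitochondrially encoded list had 7 of 10 lower and 2 higher (−0.98, adjusted p = 5.83e-04) and MHC class I presentation 11 of 18 lower (−0.36, adjusted p = 0.0348, B2m −0.79). Their adjusted p was 0.282 and 0.158 with an estimated correlation. The other 13 lists were not called, among them fatty acid oxidation (10 higher, 7 lower of 22, adjusted p = 0.956), interferon response genes (13 of 19 lower, −0.83, adjusted p = 0.120) and amino acid transporters (7 higher, 8 lower of 17, adjusted p = 0.964). The transporters and the immediate early and heat shock genes had a median or mean whose sign differed from that of the test. The MYC differences at 10 and 200 µM correlated across genes (Pearson r = 0.616, Spearman rho = 0.586), where genes are not independent replicates. Of 7353 genes that passed in both media, 6065 had the same direction. Genes higher in both numbered 3000 where independent lists would share 1696, and genes lower in both 3065 against 1737.

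In MYC high cells, 10 µM methionine went with lower ATF4 response and ribosome biogenesis genes and with higher cholesterol and fatty acid synthesis genes than 200 µM. Of 36 ATF4 response genes 32 fell and 4 rose (median log2 −1.27, camera adjusted p = 7.78e-13), and Psat1 (0.68), Vldlr (0.72), Pck2 (0.28) and Gpt2 (0.25) were those against the list. Trib3 (ENSMUSG00000032715) stood at 572 ± 15.9 at 10 µM (SD, n = 3) against 3225 ± 147 at 200 µM (SD, n = 2), a log2 change of −2.49 (SE 0.054, adjusted p = 2.53e-31). Of 24 cholesterol synthesis genes 23 rose and 1, Hsd17b7 (−0.07, adjusted p = 0.592), did not pass (median 1.97, camera adjusted p = 5.27e-12). Of the 12909 genes, 9787 passed with limma, 4893 higher and 4894 lower, and 2857 changed by at least 2-fold, 1672 higher and 1185 lower.

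Nop2 fell from 3108 ± 81.4 to 1740 ± 68.9 (log2 −0.84, SE 0.044, adjusted p = 3.10e-19) and Mat2a from 2902 ± 187 to 1551 ± 30.1 (log2 −0.90, SE 0.041, adjusted p = 4.11e-21). Slc7a5 (−0.28), Atf4 (−0.97), Asns (−0.50), Odc1 (−0.24) and Ncl (−0.45) fell, while Slc43a2 (0.35, SE 0.101) and Afp (1.19, SE 0.127) rose. Ahcy rose by 0.11 (adjusted p = 0.0187), a call that ended without replicate 3 of MYC high at 200 µM (adjusted p = 0.134) or replicate 1 of MYC high at 10 µM (adjusted p = 0.0744). Mtap stood 0.06 higher with an adjusted p of 0.254. Selenbp1 rose from 3.88 ± 0.981 to 1321 ± 69.0 (log2 8.10, SE 0.31), and Cyp2s1 (5.97), Map2k6 (5.48), Ddc (5.33) and Efhd1 (5.24) had the next largest increases. Pmepa1 (−4.98, SE 0.159), Snhg1 (−4.27), Atf3 (−4.14), Ptgs2 (−3.73) and Gpat3 (−3.61) had the largest decreases. Snhg1, a host transcript of small nucleolar RNAs, went from 9534 ± 81.0 to 493 ± 33.5, and Atf3, a stress-induced transcription factor of the ATF4 list, from 3080 ± 58.7 to 175 ± 27.5.

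Ribosome biogenesis genes fell in 50 and rose in 6 of 60 (median −0.63, camera adjusted p = 4.98e-11), with Nop58 lower 4.01-fold and Nop14 at −1.80 on the log2 scale. MYC targets fell in 28 and rose in 11 of 43 (−0.29, adjusted p = 0.0132, adjusted p = 0.324 with an estimated correlation), with Mcm4 at −1.77 and Ldha at 2.67. Amino acid transporters (11 of 17 lower, −0.64, Slc38a2 −1.92), synthetases (16 of 20, −0.55, Wars −1.83), unfolded protein response genes (16 of 23, −0.30, Hspa5 −1.37) and p53 targets (14 of 23, −0.17, Mdm2 −1.52) had camera adjusted p of 2.05e-03, 4.67e-04, 2.05e-03 and 0.0214. With an estimated correlation their adjusted p was 0.0543, 0.0930, 0.0543 and 0.184. Slc38a2 and Wars also belong to the ATF4 list. Lysosome and autophagy genes (25 of 37 lower, −0.31, Sqstm1 −2.40) and DNA and protein methyltransferases (23 of 37, −0.31, Prmt1 −0.92) were called at 1.06e-03 and 0.0219 and lost at an adjusted p = 0.237 and an adjusted p = 0.344 with an estimated correlation.

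Srebf2, which encodes the transcription factor of the cholesterol genes, rose by 2.62 (SE 0.044) in MYC high cells. Fatty acid synthesis genes rose in 19 and fell in 2 of 22 (median 0.86, camera adjusted p = 9.16e-07), with Scd2 at 3.90 and Srebf1 at 2.15, and Fasn (−0.37) and Dgat1 (−0.45) against the list. Scd2 shares sequence with Scd1 and its value is uncertain. Glycolysis genes rose in 19 and fell in 2 of 21 (1.82, adjusted p = 7.78e-13, adjusted p = 0.0534 with an estimated correlation), with Gpi1 at 2.22 and Gapdh at 1.82, and Pfkfb3 (−0.25) and Slc16a3 (−0.83) against the list. Glutathione and NRF2 targets rose in 21 of 28 (0.88, adjusted p = 3.47e-05, Ephx1 2.43) and interferon response genes in 14 of 19 with none lower (adjusted p = 9.83e-03, Bst2 2.01). These calls were lost at an adjusted p = 0.0534 and an adjusted p = 0.0552 with an estimated correlation. The interferon median was 1.33, and 0.90 with the 2 members that had 1 read at 200 µM placed at the limit nearest to no change. These were again Oas3 and Xaf1, with ratios of 60.3 (counting interval 10.6 to 2404) and 5.53 (0.767 to 243). Fatty acid oxidation genes (13 of 22 higher, 0.31, Acadm 2.42) and oxidative phosphorylation genes (28 of 43, 0.25, Ndufa8 0.98) were called at 0.0325 and 6.67e-03, with an adjusted p = 0.344 and an adjusted p = 0.496 with an estimated correlation. Ribosomal protein genes were not called, with 17 higher, 38 lower and 21 not passed of 76 (−0.09, adjusted p = 0.135). Cell cycle genes were split into 23 higher and 22 lower of 46 (adjusted p = 0.725), with Ccnb2 at 2.93 and Mcm2 at −1.70.

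In MYC low cells, all 36 ATF4 response genes fell at 10 µM methionine (median log2 −1.19, camera adjusted p = 6.92e-33) and all 24 cholesterol synthesis genes rose (0.95, adjusted p = 1.06e-14). Trib3 stood at 192 ± 5.20 against 1862 ± 32.8 at 200 µM (SD, n = 3 each), a log2 change of −3.27 (SE 0.048, adjusted p = 1.10e-35), and Pycr1 of proline synthesis at 102 ± 9.47 against 911 ± 8.09 (−3.15, SE 0.066). Ribosomal protein genes fell in 72 and rose in 3 of 76 (−0.50, adjusted p = 1.89e-32, adjusted p = 0.108 with an estimated correlation), where Rpl37a (0.19), Rpl15 (0.15) and Rpl7 (0.10) went against the list. Of the 12909 genes, 7666 passed with limma, 3801 higher and 3865 lower, and 718 changed by at least 2-fold, 438 higher and 280 lower.

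Nop2 fell by 0.15 on the log2 scale in MYC low cells (1209 ± 28.5 to 1086 ± 5.03, SE 0.039, adjusted p = 9.86e-04). Mat2a stood at 2367 ± 31.5 and 2218 ± 36.9 (log2 −0.09, SE 0.037, adjusted p = 0.0277), and this call ended without either of replicates 1 and 3 at 200 µM (adjusted p = 0.0569 and 0.0897) or replicate 2 at 10 µM (adjusted p = 0.111). Ahcy changed by 0.08 with an adjusted p of 0.0984. Slc7a5 (−0.77), Atf4 (−0.80), Asns (−1.08), Odc1 (−0.46) and Ncl (−0.62) fell, and Mtap (0.23), Slc43a2 (0.75) and Afp (0.55, SE 0.113) rose. Padi3 (3.25, SE 0.176), Ly6c1 (2.97), Cldn2 (2.61), Pax8 (2.49) and Ddc (2.43) had the largest increases, and Hrk (−3.66, SE 0.23), Ciart (−3.32) and Cdsn (−3.30) had, with Trib3 and Pycr1, the largest decreases. Ly6c1 has near-identical relatives and its value is uncertain.

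Ribosome biogenesis genes fell in 42 and rose in 6 of 60 in MYC low cells (median −0.27, camera adjusted p = 1.16e-08), with Tcof1 at −1.05 and Nop14 at −1.18. Amino acid transporters (12 of 17 lower, −0.62, Slc6a9 −2.59), synthetases (15 of 20, −0.41, Lars −1.04) and serine and folate genes (13 of 23, −0.28, Mthfd2 −2.02) had adjusted p of 7.86e-05, 2.96e-07 and 1.73e-04. Slc6a9 and Mthfd2 also belong to the ATF4 list. MYC targets (27 of 43 lower, −0.22, adjusted p = 1.05e-03, Ccnd2 −0.87, with Ldha at 1.42) and lysosome and autophagy genes (24 of 37 lower, −0.26, adjusted p = 7.86e-05, Sqstm1 −1.28) lost their calls at an adjusted p = 0.158 and an adjusted p = 0.142 with an estimated correlation. Fatty acid synthesis genes rose in 17 of 22 (0.46, adjusted p = 5.02e-09, Fasn 0.79) and fibroblast and stellate cell markers in 6 of 7 (0.85, adjusted p = 1.05e-03, Sparc 1.11, Vim 0.42). Most of the 20 fibroblast markers listed were too low to be tested. Glycolysis genes (17 of 21 higher, 0.49, Ldha 1.42), fatty acid oxidation genes (14 of 22, 0.26, Acadm 0.92) and glutathione and NRF2 targets (19 of 28, 0.26, Prdx1 0.84) were called at 8.57e-09, 6.06e-03 and 2.54e-03, and with an estimated correlation at an adjusted p = 0.0883, 0.222 and 0.108 they were not. Fetal liver and progenitor markers (9 of 16 higher, 0.47, Krt19 1.76) and MHC class I genes (10 of 18, 0.16, Calr 0.64) both had a camera adjusted p of 0.0344, with an adjusted p = 0.108 and an adjusted p = 0.141 with an estimated correlation. Calr is a chaperone of the endoplasmic reticulum. In this comparison counts adjusted over the list alone differed by at most 2 members per direction.

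The methionine response was broader and larger in MYC high than in MYC low cells. Both responses correlated across genes (Pearson r = 0.652, Spearman rho = 0.628), and the slope of the MYC low on the MYC high response was 0.361. The SD of the log2 changes over genes was 0.960 in MYC high and 0.532 in MYC low cells. Of 6449 genes that passed in both states 5577 had the same direction, with 2784 higher in both where independent lists would share 1441 and 2793 lower in both against 1465. The test of the difference itself, the interaction of MYC state and methionine, passed for 7798 of 12909 genes, 4000 with the more positive response in MYC high cells and 3798 with the more negative one, and 1657 of these differed by at least 2-fold.

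Glycolysis genes had the largest difference in response of the lists called, with 18 of 21 more positive in MYC high cells and none more negative (median 1.35, camera adjusted p = 1.38e-16). Gpi1 (1.92, SE 0.042), Pfkp (1.96) and Aldoa (1.61) were among them. Cholesterol synthesis genes were more positive in 19 of 24 (0.84, adjusted p = 1.51e-07, Srebf2 1.44) with Hsd17b7 (−0.75) against the list, fatty acid synthesis genes in 14 of 22 (0.47, adjusted p = 9.93e-04, Scd2 2.39) and glutathione and NRF2 targets in 21 of 28 (0.53, adjusted p = 1.75e-06, Gstp1 1.22). Ribosomal protein genes were more positive in 74 of 76 (0.43, adjusted p = 2.32e-19, adjusted p = 0.294 with an estimated correlation) and oxidative phosphorylation genes in 24 of 43 (0.16, adjusted p = 0.0281, adjusted p = 0.726 with an estimated correlation). Ribosome biogenesis genes were more negative in 45 of 60 (−0.42, adjusted p = 1.16e-07, Rrp12 −1.46) and unfolded protein response genes in 16 of 23 (−0.59, adjusted p = 8.37e-07, Hspa5 −1.43). The p53 targets (13 of 23 more negative, −0.32, Trp53inp1 −1.48), lysosome and autophagy genes (20 of 37, −0.17) and DNA and protein methyltransferases (19 of 37, −0.22, Ezh2 −0.70) were called at 7.37e-04, 0.0206 and 0.0404. These were lost at an adjusted p = 0.0874, 0.493 and 0.493 with an estimated correlation. The ATF4 list was not called, with 16 members more positive and 17 more negative of 36 (adjusted p = 0.782), among them Aldh18a1 at 1.26 and Atf3 at −2.75. Lists whose median, mean and test differed in sign were not called in any comparison. They were the m5C methyltransferases throughout, the salvage list in both methionine comparisons and the interaction, and the methionine cycle in MYC high cells and the interaction. The mitochondrially encoded and fetal lists in MYC high cells, the p53 and immediate early lists in MYC low cells, and the synthetase, MHC class I, hepatocyte and fibroblast lists in the interaction were others, beside the transporters and immediate early genes between the MYC labels at 10 µM.

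Of the genes fixed by name, Nop2 (−0.68, SE 0.059, adjusted p = 1.84e-12), Mat2a (−0.81, SE 0.055), Atf4 (−0.17), Mtap (−0.17, adjusted p = 0.0135) and Slc43a2 (−0.40, adjusted p = 0.0110) had the more negative response in MYC high cells. The call of Mtap ended without replicate 3 of MYC high at 200 µM (adjusted p = 0.0751), and that of Slc43a2 with edgeR and with DESeq2 (adjusted p = 0.0552 and 0.0605). Slc7a5 (0.49), Asns (0.58), Trib3 (0.78), Odc1 (0.22), Ncl (0.17) and Afp (0.64) had the more positive one, and Ahcy stood at 0.04 with an adjusted p of 0.586. Selenbp1 (7.03, SE 0.42), Cyp2s1 (4.71), Map2k6 (4.56), Bnip3 (4.22) and Ankrd37 (4.05) had the largest positive interaction. Pmepa1 (−4.46, SE 0.21), Hspa1b (−4.12), Clstn2 (−3.41), Sprr1a (−3.19) and Angptl8 (−2.86) had the largest negative one.

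**Figure D3:**
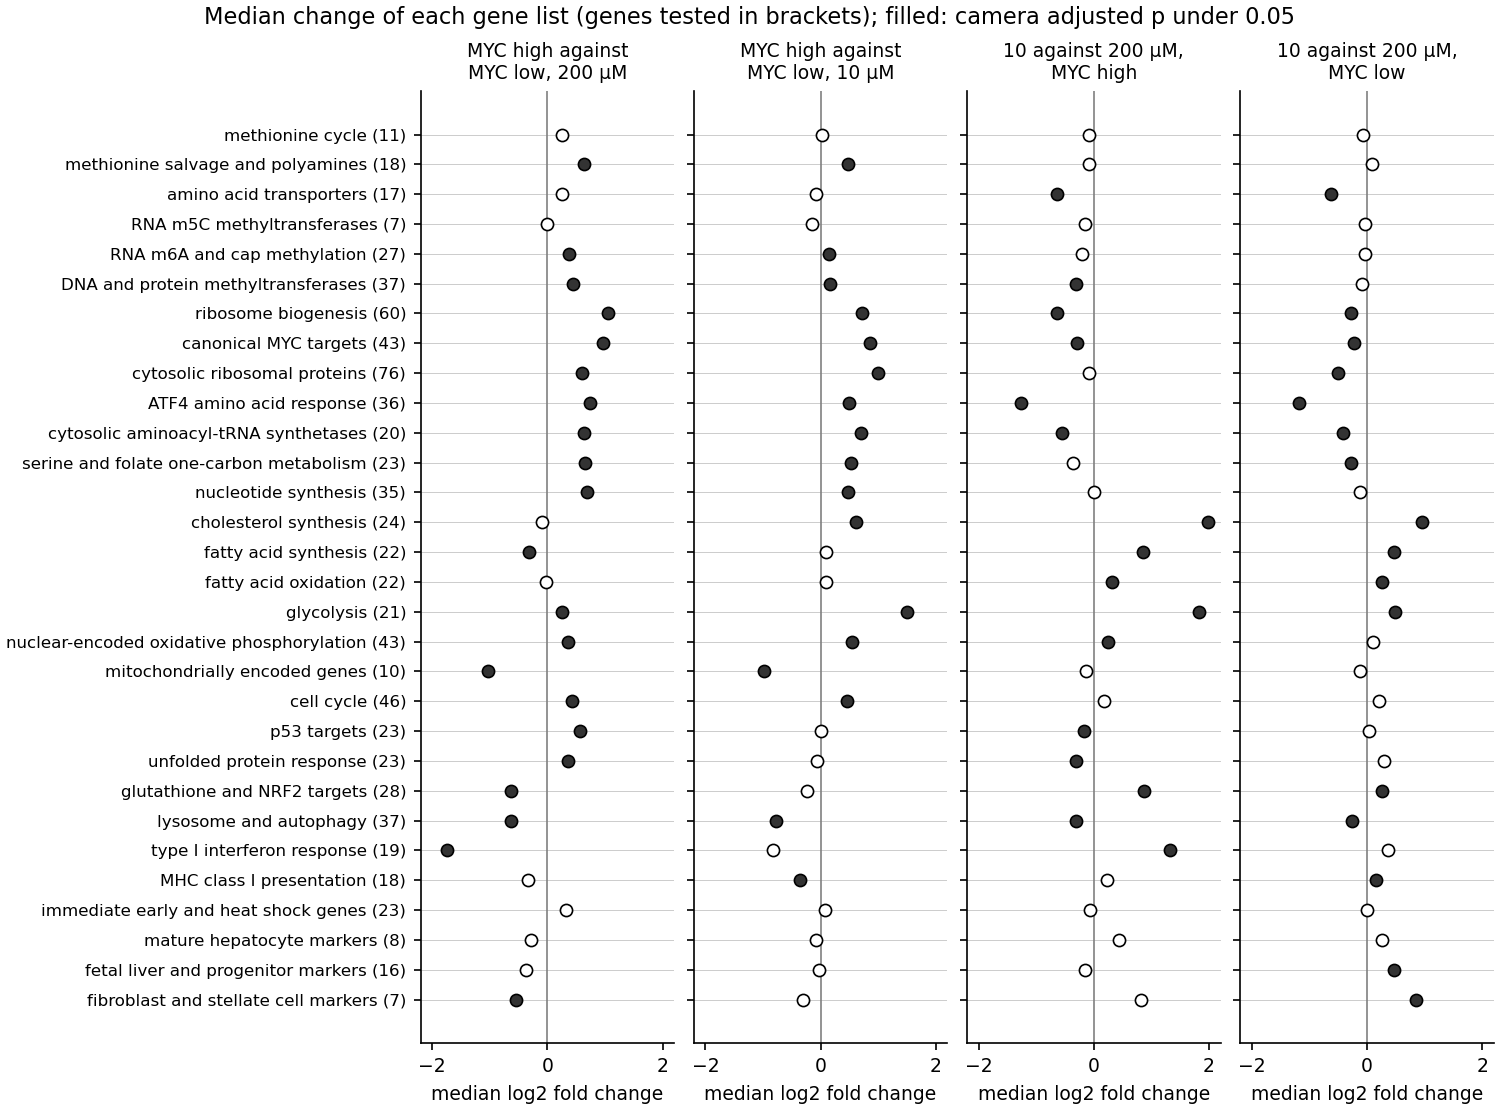
Median log2 fold change (horizontal axes) of the 30 gene lists with enough measured members (vertical axis, number tested in brackets) in the comparisons of MYC labels and of media. Filled points passed the camera test at an adjusted p under 0.05 and open points did not, and the ATF4 list lies at −1.27 and −1.19 in the panels for methionine.

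**Figure D4:**
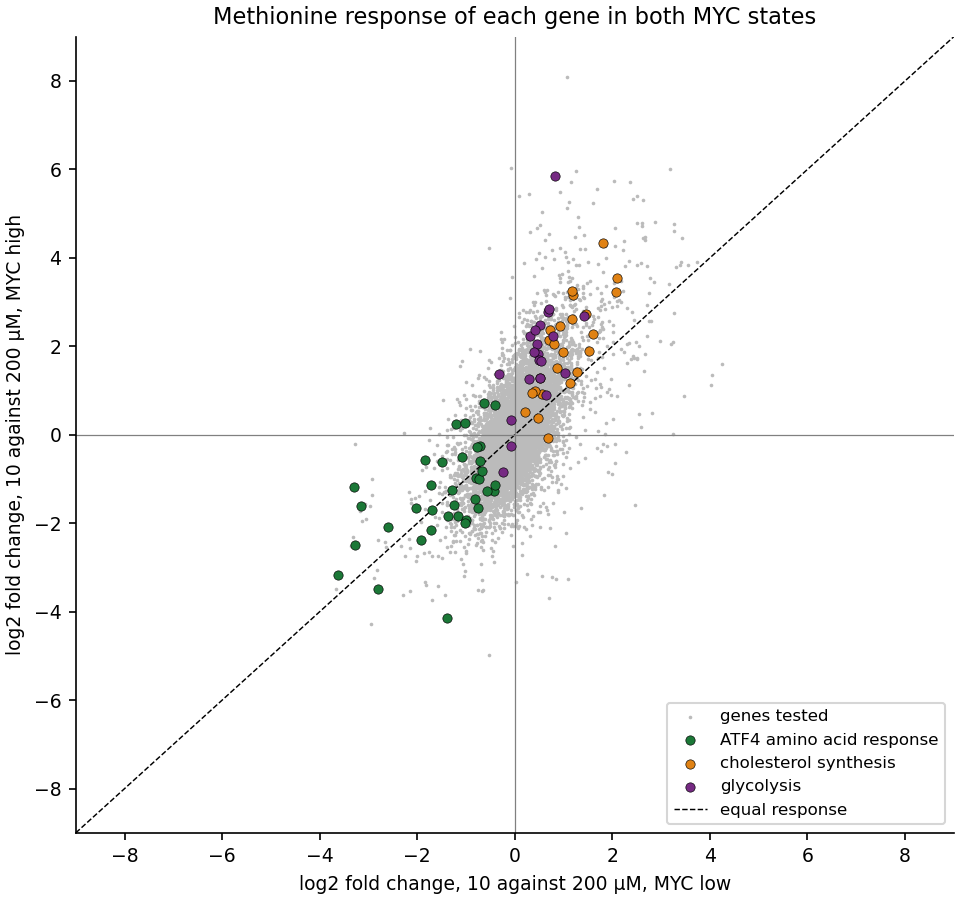
Log2 fold change of 10 against 200 µM methionine for each of 12909 genes in MYC low cells (horizontal axis) and MYC high cells (vertical axis), with the ATF4, cholesterol synthesis and glycolysis lists in colour and equal responses on the dashed line. In MYC high and MYC low cells the medians are −1.27 and −1.19 for ATF4 genes, 1.97 and 0.95 for cholesterol genes and 1.82 and 0.49 for glycolysis genes.

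The changes of MYC high cells at 10 µM methionine were also set against those that went with the MYC low label. At 200 µM the methionine changes correlated across genes with the difference of MYC low minus MYC high (Pearson r = 0.568, Spearman rho = 0.567), and of 7783 genes that passed in both 6203 had the same direction (79.7%). Both comparisons share the MYC high libraries at 200 µM. Simulated groups without any effect gave a mean r of 0.600 and 70.4% in the same direction over 100 draws. The simulated share was taken over all genes and the observed one over genes that passed in both, so these shares cannot be compared. The covariance was 0.474 against 0.0161 in the simulation. Genes higher in both numbered 3127, where independent lists would share 1840, and genes lower in both 3076 against 1799. At 10 µM, where the shared libraries enter with opposite signs, r was −0.149 and rho −0.110 against a simulated r of −0.447. The covariance was −0.115 against −0.0107. Of 7293 genes that passed in both, 3303 (45.3%) had the same direction, where the simulated share over all genes was 35.3%. Of these, 1633 were higher in both where independent lists would share 1751, and 1670 lower in both against 1748. The shared groups held 2 libraries at 200 µM and 3 at 10 µM. They were not split, since a part would have held 1 library. Part of the agreement at 200 µM may therefore come from the shared libraries. The simulated r of 0.600 follows from sharing alone in groups without changes, so it cannot be set against an r over changed genes. The covariance of 0.474 was far above the 0.0161 that the spread between libraries gave. A difference particular to the shared group as a whole would also enter both comparisons, and the simulation did not cover it. At 10 µM r was negative, and fewer genes passed in the same direction than independent lists would share.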

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

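Of the tests in this part, those on Mat2a and on genes of endoplasmic reticulum stress were written only after the result had been seen, while the other tests were written before their own values were known. What set most of these results apart was a methionine response that differed between MYC high and MYC low cells, tested by the interaction, which passed for 7798 genes with limma. The ATF4 pattern was instead chosen after its values were seen, and its medians were alike in both MYC states (−1.27 and −1.19, interaction camera adjusted p = 0.782). The groups held 2 or 3 libraries, too few to test for a single library far from the others.

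ATF4 response genes were lower in libraries labelled 10 µM, the opposite of what scarce amino acids usually do, and an exchange of the methionine labels is a candidate explanation. Mat2a rises when methionine is scarce. In MYC high cells it changed by −0.90 on the log2 scale (SE 0.041, n = 3 against 2), the direction an exchange would give. In MYC low cells Mat2a changed by −0.09 (SE 0.037), a call lost in several alternatives. That is neither the rise of scarce methionine nor a fall like that in MYC high cells. The 9 host transcripts of small nucleolar RNAs, which accumulate when translation slows, had a median change of −1.30 (SE 0.75) in MYC high and −0.53 in MYC low cells, and the exchange and a true response cannot be told apart by them. Endoplasmic reticulum stress is another source of ATF4 activity. In MYC low cells unfolded protein response genes had a median of 0.30 (SE 0.135, 23 genes), not the fall that less stress would give. The list was not called there, with 14 higher and 8 lower (camera adjusted p = 0.0902), so less stress cannot be excluded. In MYC high cells the median was −0.30 (SE 0.182), and the list was called lower (camera adjusted p = 2.05e-03, adjusted p = 0.0543 with an estimated correlation). Less stress may contribute there. Media depleted of other amino acids could not be tested, and the exchange stays open.

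Glycolysis genes had a median interaction of 1.35 on the log2 scale, with MYC high cells at 10 µM far above the rest. Lower oxygen in those cultures is a candidate explanation, since 22 genes induced by low oxygen outside glycolysis and not seen before had a median interaction of 1.20 (SE 0.130). Bnip3 (4.22) and Ankrd37 (4.05), both known targets of hypoxia-inducible factors, were set apart in the same way. The glycolysis median was 1.29 (SE 0.21) after the trend on transcript length and GC content was removed. A bias that follows these values is therefore unlikely, but expressed transcripts can be shorter than the longest annotated ones used. Oxygen was not measured, and denser cultures or a metabolic change that stabilizes these factors were not tested.

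Ribosomal protein genes moved together, with a median interaction of 0.43 (adjusted p = 0.294 with an estimated correlation), and their short transcripts could carry a length bias. Their median difference between MYC high and MYC low cells at 10 µM was 0.99 before and 0.92 (SE 0.0208, 76 genes) after the trend on length and GC content was removed. Their methionine response in MYC low cells was −0.50 before and −0.54 (SE 0.0215) after. A bias by length or GC content of the longest annotated transcript is thus an unlikely whole source of either. The interaction shrank from 0.43 to 0.37 (SE 0.0218), of which the bias may account for that part, while the response in MYC high cells, where the list was not called, grew from −0.09 to −0.17 (SE 0.0447). Other differences in library preparation were not tested.

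The other lists set apart by the interaction had medians of 0.84 for cholesterol synthesis, 0.47 for fatty acid synthesis, 0.53 for glutathione and NRF2 targets, 0.16 for nuclear-encoded oxidative phosphorylation, −0.42 for ribosome biogenesis, −0.59 for the unfolded protein response, −0.32 for p53 targets, −0.22 for DNA and protein methyltransferases and −0.17 for lysosome and autophagy genes. With an estimated correlation the calls of oxidative phosphorylation (camera adjusted p = 0.726), p53 targets (0.0874), DNA and protein methyltransferases (0.493) and lysosome and autophagy genes (0.493) were lost. Among the genes that the naming rule gives for the interaction, single genes were set apart where the response differed at least 8-fold between the MYC states, a value of 3 on the log2 scale. Besides Bnip3 and Ankrd37 these were Selenbp1 (7.03), Cyp2s1 (4.71), Map2k6 (4.56) and Gamt (3.24) on the positive side and Pmepa1 (−4.46), Hspa1b (−4.12), Clstn2 (−3.41) and Sprr1a (−3.19) on the negative side. Oas3 (3.84) had 1 read in the MYC high libraries at 200 µM, and its value depends on the pseudocount.

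Each of the 10 ways to split the 6 libraries into 2 groups was also fitted for the comparison of MYC labels at 10 µM and of media in MYC low cells. The real split gave 9232 and 7666 genes with limma and the highest other split 0 in both, and for lists the real split gave 17 and 16 against 16 and 15. In each case 1 split, the real one, reached the real count, but 10 splits are too few for a share under 0.05. Every other split also mixed libraries of both groups, so the real difference entered its spread and, in part, its contrast. The counts of those splits therefore do not show how many calls arise without a difference.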

How the results depend on the processing

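The tests here were chosen before the results were seen, apart from the count of at least 2-fold changes, which was chosen only after. No named gene changed direction in a call under any alternative, and neither did any list called both in the main test and in the alternative. Fry called immediate early and heat shock genes lower between the MYC labels at 10 µM (fry adjusted p = 1.65e-03). It did so too for media in MYC low cells (fry adjusted p = 0.0131). Camera had given both the upward direction without a call. Of 15078 alternative results for named genes 15041 had the same call, 33 lost it and 4 gained it. Most named genes were picked for a small adjusted p or a large difference, which favours keeping a call. Over all genes with a call, losses were larger in some alternatives. DESeq2 kept 6932 of the 7798 calls of the interaction, and the fit without a filter 7008 of 7666 for media in MYC low cells. Of 3415 alternative results for lists 3262 had the same call, 71 lost it and 82 gained it. Most of these gains came with fry, which asks whether a list changed at all rather than more than other genes. Total-sum scaling moved the balance of calls between the MYC labels to 4148 higher and 5438 lower genes at 200 µM and to 4169 and 5088 at 10 µM, so the near-even splits depend on the scaling. DESeq2 called 8996, 8716, 9240, 7050 and 6933 genes in the comparisons of MYC labels at 200 and 10 µM, of media in MYC high and MYC low cells and in the interaction, and edgeR called 9583, 9386, 9718, 7915 and 7757. At least 2-fold changes numbered 2798 without a filter against 1851 with it between the MYC labels at 10 µM, and 1222 without a filter or 427 at a mean of at least 50 against 718 for methionine in MYC low cells. With an estimated correlation 7, 8, 4, 8 and 6 lists were called in the same order instead of 21, 17, 16, 16 and 11, and with fry 30, 28, 27, 27 and 26. Leaving out 1 library gave 8890 to 9659, 8786 to 9317, 9088 to 9788, 7137 to 7776 and 7239 to 7647 genes, and 9 to 11 lists in the interaction, not always the same ones. Without replicate 2 of MYC high at 200 µM, for instance, the interferon list gained a call (camera adjusted p = 0.0485) and DNA and protein methyltransferases lost theirs (0.0654). Mat2a in MYC low cells lost its call without a filter (limma adjusted p = 0.0602), with total-sum scaling (0.0792), without a trend (0.0805) and with DESeq2 (0.0582), and glycolysis between the MYC labels at 200 µM lost its call without a trend (0.106). Interferon genes in MYC high cells lost theirs at a mean of at least 50 (0.0832). Libraries share replicate numbers but no stated pairing, and residuals of libraries with the same number correlated at −0.0490 to 0.0257 against −0.0464 to 0.0490 for other numbers, with 2 of 11 closest to their own number. With the replicate block limma called 9495, 9214, 9668, 7653 and 7663 genes and the same numbers of lists.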

Other observations

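The lists and the cell cycle split in the next sentences were written only after the data were seen, and the test of the low-oxygen list left out the genes seen before. Cell cycle genes were divided by known function into those of DNA replication and those of mitosis, which moved in opposite directions in MYC high cells at 10 µM methionine. All 20 replication genes fell, with a median of −1.20 on the log2 scale, as in Mcm2 (5492 to 1688 normalized counts) and Mcm3 (7084 to 2294), which encode parts of the replicative helicase. Of 26 mitosis genes 23 rose and 2 fell (median 1.02), as in Ccnb2, a mitotic cyclin (200 to 1528). In MYC low cells 15 of 20 replication genes fell and 2 rose (−0.46), and 23 of 26 mitosis genes rose and 2 fell (0.57). Between the MYC labels at 200 µM, 18 replication genes were higher and none lower (1.11), while mitosis genes were higher in 11 and lower in 9 (0.04). At 10 µM both parts were mostly higher in MYC high cells, replication genes in 14 with 4 lower (0.39) and mitosis genes in 22 with 1 lower (0.51). Replicated DNA was not measured.

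Low-oxygen genes outside glycolysis were higher in MYC high than in MYC low cells at 10 µM in 24 of 27 and lower in 2 (median 1.23). They rose with the lower methionine in 23 and fell in 3 in MYC high cells (1.06), and rose in 11 and fell in 13 in MYC low cells (−0.12). Host transcripts of small nucleolar RNAs fell in 9 of 13 and rose in 3 in MYC high cells (median −1.48), and fell in 10 and rose in 2 in MYC low cells (−1.40). Without the 4 members seen before, the medians of the other 9 were −1.30 (SE 0.75) and −0.53 (SE 0.60), so the genes seen before carried much of the decrease in MYC low cells. Of the 13, 11 were higher in MYC high cells at 200 µM (0.98) and 12 at 10 µM (0.87). Markers of other cells were measured beside them. Of the macrophage list, Cd68 stood at 28.2, 88.9, 454 and 204 normalized counts in MYC high and MYC low cells at 200 µM and MYC high and MYC low cells at 10 µM, Csf1r at 246, 420, 435 and 744, and Cd14 at 385, 430, 205 and 392. Of the endothelial list, Flt1 stood at 597, 267, 576 and 111 in the same order, Stab1 at 3.26, 12.8, 22.3 and 38.6, Eng at 46.6, 46.0, 85.6 and 76.0, and Egfl7 at 119, 157, 433 and 218. The median marker of the whole lists stood at 0.0802 normalized counts over 21 macrophage genes and 0.649 over 15 endothelial genes, so most of these markers were near 0. The source of those that were expressed was not tested.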
